A study of Mus musculus with 5 samples.

How the data were processed

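RNA was measured in 5 libraries of mouse bone marrow late pre-B cells, 3 labelled Control and 2 labelled DCKO (double conditional knockout of Zfp36l1 and Zfp36l2). Per the labels' protocols, cells were sorted as CD19 positive, IgM negative, CD43 negative and CD25 positive, RNA was extracted with Trizol, and 0.1 µg was made into TruSeq libraries that kept strand by the dUTP method. Per the labels, both groups carry floxed alleles of both genes, and the groups differ in the Mb1 locus, which is wild type in Control and carries cre on 1 allele in DCKO. Every difference between the groups is therefore also one of cre against no cre, and the deletion cannot be separated from it. Replicate numbers and groups were taken from the sample titles. Nothing in the labels says whether libraries came from separate animals. Y-linked transcripts had 12513 counts in Control 3, 10493 in DCKO 2, 11 in DCKO 1 and 0 in Control 1 and 2. The 2 DCKO libraries thus came from different animals or pools, as did Control 3 and the other Control libraries. Whether Control 1 and 2 did is not known. The p-values measure the spread between these libraries, which may in part be technical.

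Per the submitters' processing notes, Trim Galore, TopHat 1.1.4, the NCBIM37 genome build and DESeq 1.12.1 were used, with no role or order given. The read counter, its annotation and its strand setting are not given in the sources used here. The authors deposited whole-number counts per gene for 22232 Ensembl genes, which summed to 42730752, 39002587 and 38709263 in Control 1, 2 and 3 and to 36474257 and 37576753 in DCKO 1 and 2. A second deposited table holds log2 values of the same libraries. Their rank order equals that of counts divided by median-ratio size factors (lowest Spearman correlation over libraries 1.0), and the 7918 genes without any read sit at 8.26, so these values were used for this check alone. The authors' deposited comparison table, per the file headers, holds mean normalized signal per group (counts over size factors), a linear fold ratio of DCKO over Control, and a p-value with its adjusted value. Its column of log2 fold changes holds text errors and was not used; the linear ratio was used instead. The table was compared with the fit described next and entered no test.

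Gene symbols came from the GENCODE annotation of NCBIM37, with 2159 older symbols updated, and all 22232 identifiers matched. In 23 rows of the count table the identifier carried trailing text, which was removed. Immunoglobulin segments annotated as such were not in the count table; 10 genes with immunoglobulin names were. Genes with near-identical copies appear undercounted. Of 88 ribosomal protein genes, 65 had a mean under 10 CPM (counts scaled to library size), and Gapdh had 0.278 CPM against 2400 CPM for Actb, so values of multicopy genes (ribosomal protein genes, histones, Vpreb1 with Vpreb2, Iglc2 with Iglc3) are uncertain. Zfp36l1, Ccnd3, Vpreb1, Arpp21, Tyms, Cdc45, Cd72, Bst1, Jun, Pim1, Atf5 and several other named genes overlap an annotated gene on the opposite strand, and with the strand setting unstated reads of such a pair cannot be told apart.

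The deposited counts were fitted with edgeR 4.0.16 in R 4.3.3: filterByExpr by group, which left 11406 genes, TMM scaling, and the quasi-likelihood F test of DCKO minus Control with no covariate. Adjusted p-values are Benjamini-Hochberg values at a threshold of 0.05, and a gene is called when it passes. CPM values are scaled by TMM, and values are given as mean ± SD over 3 Control and 2 DCKO libraries. The standard error of a log2 fold change is its size over the root of the F statistic. Before the data were examined, 30 gene lists were written. They were tested with camera (limma 3.58.1) at a preset correlation of 0.01, adjusted over the 29 lists with more than 1 tested gene, and again with an estimated correlation. Camera compares a list with other genes; fry, also run, tests it against no change. Single values were compared by exact two-sided permutation, which cannot go below p = 0.1 for 3 against 2 libraries. The immunoglobulin share was expressed as CPM of the library total.

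Named genes followed a rule also written before the data were examined. It took Zfp36l1, Zfp36l2, Zfp36 and Cd79a; the 10 largest and 10 smallest log2 fold changes among genes called with a mean of at least 10 CPM and no overlap of CPM between groups, leaving out immunoglobulin segments and genes with clone or small RNA names; and up to 4 called members of each list with the smallest adjusted p, or the 2 most abundant where none was called. For a group at 0 counts, the fold was bounded with a floor of 3 counts per library.

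The AU-rich heptamer TATTTAT was searched in the longest annotated 3' UTR of 11227 of the 11406 tested genes (98.4%); the other 179 had no annotated 3' UTR and were not searched. A logistic regression (statsmodels 0.14.6) of being called, against not called, included log2 UTR length, AT share and mean log2 CPM. The 20 other arrangements of the same bases were run the same way. Intervals are 95% intervals across genes, which are not independent replicates.

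The scripts were tested on simulated counts of the 11406 genes in the DCKO against Control design, with 200 genes changed. Of 50 genes each, 70% were recovered at a log2 change of 1, 62% at -1, 90% at 2 and 92% at -2, and 5 of 11206 unchanged genes were called. Each simulated gene had the spread that the fitted trend gives for its expression level, with none particular to that gene. Fewer genes were changed than were called in the data. These rates check the scripts and need not hold for the real libraries. In simulated calls over 11227 genes, the 95% interval of the odds ratio held the true value in 91% of 200 draws at an odds ratio of 1 and in 96% at 1.5. Alternatives were other scaling (DESeq2 size factors, upper quartile), immunoglobulin genes left out, other filters, DESeq2 1.42.0, limma-voom, robust edgeR, the replicate number as a block, each library left out, and other motif and UTR choices. A term for Y-linked transcripts and a fit without the libraries that hold them were added after the data were seen.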

Results

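Messenger RNA was profiled in late pre-B cells, the bone marrow stage at which large cycling precursors have become small cells that rearrange immunoglobulin light chain genes. The series compared 3 Control libraries with 2 DCKO libraries, in which cre at the Mb1 locus (another name of Cd79a) acts on floxed Zfp36l1 and Zfp36l2. Both genes encode zinc finger proteins that bind AU-rich elements in mRNA and promote its decay. Total counts ran from 36474257 to 42730752 per library. Between libraries of 1 group, counts differed by far more than sampling noise, with chi-square per degree of freedom from 21 to 58.2. No library was thus a repeat of another that differed by sampling noise alone. For Control 1 and 2, separate preparations of the same RNA are not excluded by this. On a principal component analysis of log2 CPM the component with 59.8% of the variance separated the groups. Control 3 (-19.3) lay closer to the DCKO libraries (61 and 38) than Control 1 (-40.8) and Control 2 (-39) did. On the next component, with 20% of the variance, Control 1 (10.9), Control 2 (10.2) and DCKO 1 (32.2) were above 0. Control 3 (-15.7) and DCKO 2 (-37.5), the libraries that held Y-linked transcripts, were below 0.

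Transcripts of both targeted genes were strongly reduced in each DCKO library. Zfp36l1 (ENSMUSG00000021127; NCBIM37 chromosome 12, 81208747 to 81214000, minus strand) had 50.7, 24.8 and 61.5 CPM in Control 1, 2 and 3 and 1.34 and 1.53 CPM in DCKO 1 and 2. Its level was 45.7 ± 18.8 CPM (SD, n = 3) in Control and 1.44 ± 0.136 CPM (SD, n = 2) in DCKO, a log2 fold change of -4.99 ± 0.44 (SE; edgeR adjusted p = 0.00181). Zfp36l2 (ENSMUSG00000045817; chromosome 17, 84583271 to 84587287, minus strand) had 29.0, 53.1 and 29.8 CPM in Control and 4.22 and 4.74 CPM in DCKO, a log2 fold change of -3.06 ± 0.31 (SE; edgeR adjusted p = 0.00295). The third family member, Zfp36, was at 89.0 ± 14.6 CPM (SD, n = 3) in Control and 88.1 ± 9.84 CPM (SD, n = 2) in DCKO, which did not pass the edgeR test (log2 fold change -0.01, adjusted p = 0.956). Of the 3 tested members of this family list, 2 were lower and 1 did not pass, also when adjusted over the list alone (camera adjusted p = 1.07e-05; adjusted p = 0.29 with an estimated correlation). Cd79a, the locus that carries cre, was 1.75-fold lower in DCKO (316 ± 15.6 against 180 ± 20.3 CPM, edgeR adjusted p = 0.00474). Because cre sits on 1 allele of this gene in DCKO alone, this fall cannot be read as a response to the deletion. Gene counts do not separate the deleted part of a gene from the rest, and the remaining DCKO reads were not assigned to exons.

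**Figure D1:**
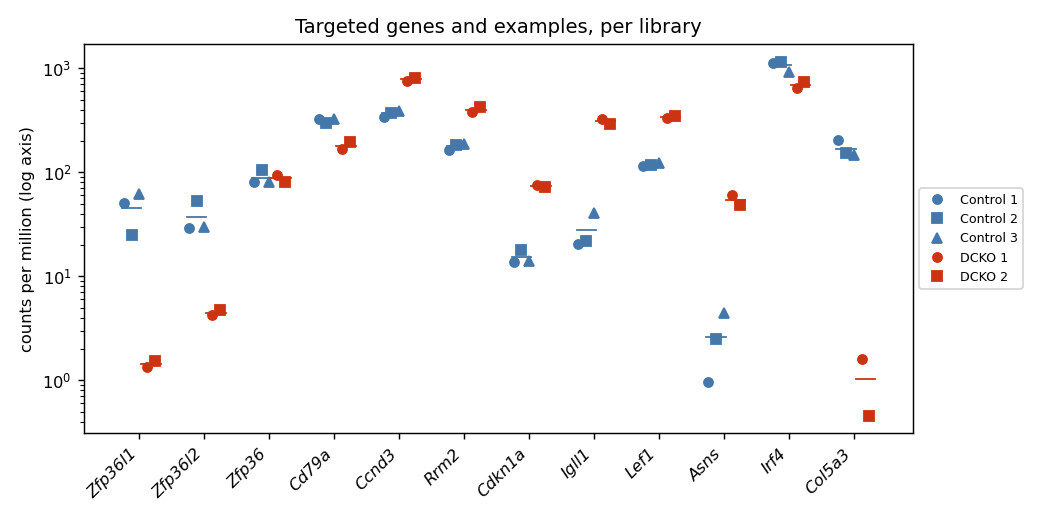
Library-scaled counts (CPM, log axis) of the targeted genes and of examples from the text in each library, with blue symbols for the 3 Control and red for the 2 DCKO libraries and short lines at the group means. Zfp36l1 lies at 1.34 and 1.53 CPM in DCKO and at 24.8 CPM or more in Control, while Zfp36 overlaps between the groups.

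Of 11406 genes tested, 1097 were higher and 793 lower in DCKO (edgeR, adjusted p threshold 0.05), so that 58% of the 1890 called genes were higher. At least 2-fold changes were seen for 399 higher and 221 lower genes. Among called genes with a mean of at least 10 CPM, those with the largest increase were Il9r, an interleukin receptor chain (0.631 against 58.8 CPM, log2 fold change 6.55), Fcer2a, the low-affinity IgE receptor CD23 (5.27), Siglech (4.70), Arpp21 (4.54), Rflnb (4.43), the asparagine synthetase gene Asns (4.39), Vpreb1 (3.83), Erg (3.68), Igll1 (3.48) and Tmem255a (3.31). Vpreb1 and Igll1 encode the surrogate light chain, and Erg an ETS family transcription factor. The largest decreases among such genes, beside the targeted ones, were those of Col5a3, a collagen chain (168 against 1.02 CPM, log2 fold change -7.36), Nav2 (-3.28), Prg3 (-2.81), Appl2 (-2.47), Pdk2 (-2.36), the insulin receptor substrate gene Irs1 (-2.26), P2rx3 (-2.25) and Itga9 (-2.17). Prg3 (84828353 to 84834043) and P2rx3 (84838740 to 84877619) lie close together on chromosome 2, so their decreases may not be separate. Siglech differed between the DCKO libraries, with 43.5 CPM in DCKO 1 and 5.89 CPM in DCKO 2, and lost its call without Control 2, without DCKO 1, with limma-voom and with robust edgeR. Prg3 lost its call without Control 1, Control 2 or either DCKO library and with the same tools, P2rx3 without either DCKO library and Irs1 without Control 2. Counts of called genes fell to 412 higher and 231 lower without Control 1 and to 307 and 166 without Control 2. They rose to 1381 and 1012 without Control 3, and fell without DCKO 1 or DCKO 2. No called gene changed direction in any fit that left out 1 library. This was nearly fixed in advance, since the groups did not overlap in CPM for any of the 1097 higher and 793 lower genes.

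**Figure D2:**
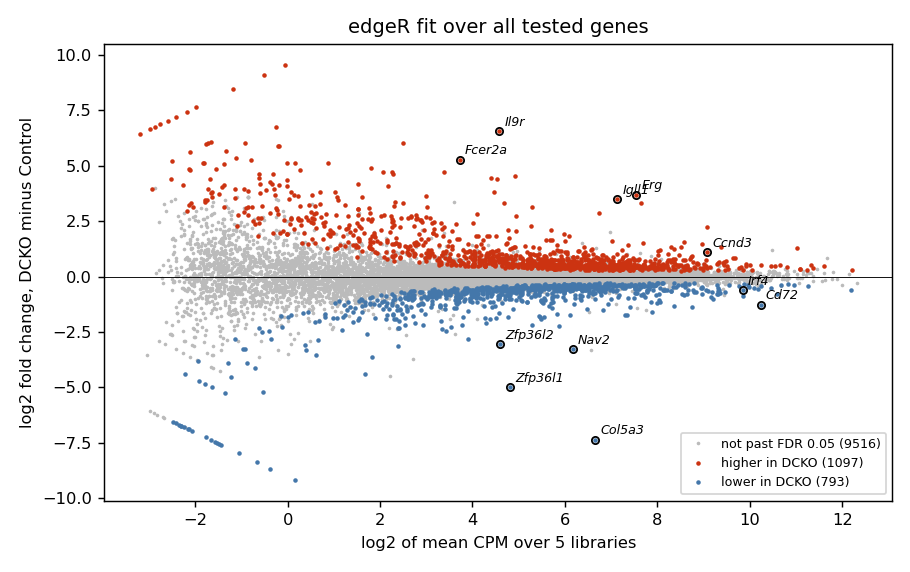
Log2 fold change (DCKO minus Control) against the log2 mean CPM of the 11406 tested genes, red for the 1097 called higher and blue for the 793 called lower by edgeR, grey for the rest. Il9r, Fcer2a, Erg and Igll1 lie far above 0 and Col5a3 at -7.36, below both targeted genes.

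Several genes that drive entry into S phase rose in DCKO. Of 17 tested cyclins, kinases and activators of the G1 to S step, 10 were higher, 0 lower and 7 did not pass; 11 were higher when adjusted over the list alone. The D-type cyclin gene Ccnd3 rose from 369 to 784 CPM (log2 fold change 1.09 ± 0.09 SE), and the E-type cyclin gene Ccne1 (1.14), the phosphatase gene Cdc25a (0.92) and Tfdp1, a partner of E2F factors (0.98), rose as well. The median log2 fold change of the list was 0.82 (camera adjusted p = 7.1e-09; adjusted p = 0.29 with an estimated correlation). DNA replication genes followed, with 29 of 50 higher, 0 lower and 21 not past the test, and 37 higher when adjusted over the list alone. Among them were the ribonucleotide reductase gene Rrm2 (177 against 401 CPM on average, log2 fold change 1.18), the thymidylate synthase gene Tyms (1.36), Cdc45 (0.84) and the helicase subunit gene Mcm4 (0.71). Their median was 0.51 (camera adjusted p = 2.85e-14; adjusted p = 0.52 with an estimated correlation). Of 51 G2 and mitosis genes, 14 were higher, 0 lower and 37 not past the test (25 higher when adjusted over the list alone), with a median of 0.28; Cdk1 (0.57), Ndc80 (0.65), Lbr (0.49) and Bub1 (0.50) were examples (camera adjusted p = 1.07e-05; adjusted p = 0.624 with an estimated correlation; fry adjusted p = 0.111). Without Control 1, Control 2, DCKO 1 or DCKO 2, the genes called higher numbered 14, 10, 14 and 11 for DNA replication, 7, 6, 4 and 6 for the G1 to S step, and 2, 2, 0 and 4 for G2 and mitosis. The G2 and mitosis genes called higher were 6 with a term for Y-linked transcripts and 26 with DESeq2. All 4 named G2 and mitosis genes lost their calls without DCKO 1. Lbr, Ndc80 and Bub1 lost theirs also without Control 2, Ndc80 and Bub1 also without Control 1, and Lbr and Bub1 also without DCKO 2.

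Inhibitors of the cell cycle went both ways. Cdkn1a, the gene of the cyclin-dependent kinase inhibitor p21, rose 4.85-fold (log2 fold change 2.28), and Rb1 rose by a log2 fold change of 0.44, whereas Klf4 (-2.58) and Tob1 (-0.91), both known to restrain proliferation, fell. Of 26 members 4 were higher, 3 lower and 19 did not pass, with the same counts when adjusted over the list alone (camera adjusted p = 0.943). Of 17 tested replication-dependent histone genes, 1 was higher (H2bc21, 0.51) and 1 lower (H1f5, -1.68), and 15 did not pass (0 higher and 1 lower adjusted over the list alone; camera adjusted p = 0.493). Most histone mRNAs lack poly(A) tails and their genes are near-identical copies, which limits both values. The calls of Rb1, H2bc21 and H1f5 were lost when either of Control 1 and 2 or either DCKO library was left out, that of Tob1 without Control 1, Control 2 or DCKO 1, and that of Klf4 without DCKO 1; inhibitors called higher numbered 1 in each of these fits.

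Several genes of the earlier pro-B and large pre-B stages were higher in DCKO. Of 19 tested, 9 were higher, 0 lower and 10 did not pass (11 higher and 1 lower adjusted over the list alone), with a median fold of 2.72. Besides Igll1 and Erg they included Kit, the stem cell factor receptor (1.98 against 17.3 CPM, log2 fold change 3.13), and the transcription factor gene Lef1 (118 against 339 CPM, log2 fold change 1.52). The camera adjusted p was 2.41e-14 (adjusted p = 0.29 with an estimated correlation). Control 3 was the highest Control library for this list, with a median log2 value 0.35 above the Control mean, against 1.40 and 1.46 in the DCKO libraries. Immature and mature B cell genes had 7 of 25 higher, 1 lower and 17 not past the test (8 higher and 1 lower adjusted over the list alone). Their median was 0.58, and ranged from 0.44 to 1.02 over left-out libraries. Fcer2a, Cd22 (1.33), Cd40 (1.07) and Gpr183 (1.98) were higher (camera adjusted p = 3.92e-04; adjusted p = 0.624 with an estimated correlation; fry adjusted p = 0.153). Here Control 3 stood 0.47 above the Control mean, close to DCKO 2 at 0.49, and the genes called higher numbered 2, 1, 14 and 1 without Control 1, Control 2, Control 3 or DCKO 1. The call of Cd40 was lost without Control 2 or DCKO 1, and those of Cd22 and Gpr183 without any 1 library except Control 3, that of Cd22 also with robust edgeR.

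Genes of the pre-B cell receptor and its signalling split, with 10 of 35 higher, 4 lower and 21 not past the test (14 higher and 4 lower adjusted over the list alone; camera adjusted p = 0.0654). The surrogate light chain genes Igll1 and Vpreb1 and the ectoenzyme gene Bst1 (1.34) were higher. Cd72, a B cell co-receptor gene, fell from 1570 to 649 CPM (log2 fold change -1.27). The lower genes also included Cd79a, which carries cre in DCKO. Among 30 B lineage transcription factors, 5 were higher, 2 lower and 23 not past the test (7 higher and 3 lower adjusted over the list alone; camera adjusted p = 0.176). Lef1 and Erg rose, while Aff3 (-0.62) and Irf4 (-0.63), a regulator of light chain rearrangement, fell; the call of Irf4 was lost without Control 1, Control 2 or DCKO 1. Of 16 genes of V(D)J recombination and end joining 2 were higher, 0 lower and 14 did not pass, also when adjusted over the list alone. In other fits, 1 was lower without Control 2 or with a term for Y-linked transcripts, 2 without Control 3 or without both Control 3 and DCKO 2, and 3 with DESeq2. The 2 higher genes were Dntt, the terminal transferase gene (log2 fold change 3.15), and Hmgb2 (0.76), and the list as a whole did not differ from other genes (camera adjusted p = 0.736). Plasma cell genes had 1 of 6 higher (Mzb1, 0.36) and 1 lower (Prdm1, -1.08), with 4 not past the test, and 2 each way adjusted over the list alone (camera adjusted p = 0.728). The call of Hmgb2 was lost without DCKO 1, that of Prdm1 without any 1 library except Control 3, and that of Mzb1 without any 1 library. Without Control 1 or Control 2, the genes called higher numbered 6 each time for the pre-B cell receptor and 2 each time for the transcription factors. Fewer were called higher in both lists without DCKO 1 or DCKO 2 as well. Of the transcription factors, 1 was lower without Control 1 or Control 2, and 8 were higher and 5 lower without Control 3. Camera passed for the pre-B cell receptor without Control 1 (adjusted p = 0.0292) or without a filter on low counts (adjusted p = 0.0329) and for both lists without Control 3 (adjusted p = 1.35e-04 and 0.00495) or without both Control 3 and DCKO 2 (adjusted p = 6.17e-04 and 0.00571), among other fits. With all libraries and an estimated correlation neither list passed (adjusted p = 0.624 for the pre-B cell receptor and adjusted p = 0.52 for the transcription factors).

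Some amino acid and unfolded protein response genes were higher in DCKO. Of 25 tested, 10 were higher, 1 lower and 14 did not pass (12 higher and 2 lower adjusted over the list alone), with a median of 0.40. Asns rose from 2.61 to 54.3 CPM, Mthfd2, of mitochondrial one-carbon metabolism, by a log2 fold change of 1.66, and the stress-response genes Trib3 and Atf5 by 2.40 and 1.21 (camera adjusted p = 2.06e-06; adjusted p = 0.29 with an estimated correlation). Transcripts reported to be bound by this protein family had 10 of 31 higher, 2 lower and 19 not past the test (12 higher and 4 lower adjusted over the list alone; median 0.50). Vegfa (log2 fold change 2.09), the kinase genes Lats2 (0.98) and Pim1 (0.65), and Tnf (3.94, at 1.18 CPM in DCKO) were higher (camera adjusted p = 0.00573; adjusted p = 0.29 with an estimated correlation). The calls of Trib3, Vegfa and Tnf were lost without DCKO 1, where 4 amino acid and unfolded protein response genes were higher. Transcripts reported to be bound that were called higher numbered 6 without Control 1, 2 without DCKO 1 and 6 without DCKO 2.

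Most other lists did not stand apart from the remaining genes by camera. Apoptosis and p53 response genes had 5 of 40 higher and 2 lower, with 33 not past the test and the same counts adjusted over the list alone; Cdkn1a, the ubiquitin ligase gene Mdm2 (0.71) and the pro-apoptotic Bcl2l11 (0.61) were higher and Casp9 lower (-0.82), and the list's median (-0.03) and mean (0.09) differed in sign (camera adjusted p = 0.492). The mRNA decay machinery had 2 of 37 higher, Cnot7 (0.43) and Cnot9 (0.44), and 35 not past the test (1 higher adjusted over the list alone; camera adjusted p = 0.736). Ribosomal protein genes had 1 of 76 higher (Rps11, 0.53) and 2 lower (Rpl22, -0.49, and Rpl31, -0.76), with 73 not past the test (1 higher and 0 lower adjusted over the list alone, camera adjusted p = 0.417). Those called lower numbered 0 without Control 1 or Control 2, 4 without Control 3 and 5 with DESeq2. Ribosome biogenesis had 2 of 30 higher (Ncl, 0.35, and Nop58, 0.37) and 28 not past the test (0 adjusted over the list alone; camera adjusted p = 0.417). Glycolysis and hypoxia had 2 of 27 higher (Vegfa and Ldha, 0.65) and 25 not past the test, as when adjusted over the list alone (camera adjusted p = 0.417, fry adjusted p = 0.0394). Cholesterol biosynthesis had 2 of 21 higher (Dhcr24, 1.69, and Hsd17b7, 0.86) and 19 not past the test, as when adjusted over the list alone (camera adjusted p = 0.197). Interferon response genes had 3 of 31 higher, 1 lower and 27 not past the test (2 higher and 1 lower adjusted over the list alone; camera adjusted p = 0.643); Ifit2 (0.80), Usp18 (0.86) and Oas3 (1.53) were higher and Ddx58 lower (-0.45). Immediate early and heat shock genes had 1 of 21 higher (Hsp90aa1, 0.66), 1 lower (Jun, -1.79) and 19 not past the test (0 adjusted over the list alone, camera adjusted p = 0.728). Without Control 3, 0 of these genes were higher and 4 lower. None of 7 mitochondrially encoded transcripts passed, also when adjusted over the list alone, and mt-Cytb and mt-Nd1 had log2 fold changes of 0.22 and 0.26 (camera adjusted p = 0.197). Of the called genes named for these lists, Cdkn1a, Mdm2 and Hsd17b7 kept their calls whichever library was left out, and each of the others lost its call in at least 1 such fit. Without Control 1, Control 2, DCKO 1 or DCKO 2, the apoptosis and p53 response genes called higher numbered 3, 2, 2 and 3, and 0 interferon response genes were higher without Control 1, Control 2 or DCKO 1 (6 without Control 3).

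Some markers of other cell types were higher in DCKO. Of 14 tested neutrophil, monocyte and dendritic genes, 3 were higher, 0 lower and 11 did not pass (4 higher adjusted over the list alone). They were Siglech, a receptor gene of plasmacytoid dendritic cells, F13a1 (11.9 against 50.5 CPM, log2 fold change 2.09) and Itgam (115 against 229 CPM, log2 fold change 0.99). The list passed camera (adjusted p = 0.0292; adjusted p = 0.52 with an estimated correlation), but not without DCKO 1 (adjusted p = 0.251) or with a filter of at least 1 CPM in 2 libraries (adjusted p = 0.0891). By fry, which tests the list against no change and not against other genes, it did not pass (adjusted p = 0.111). Its genes called higher numbered 1 without Control 2, 0 without DCKO 1 and 9 without DCKO 2. Of 8 tested T and NK cell genes, 4 were higher and 4 did not pass, also when adjusted over the list alone. Thy1, Cd4, Il2rb and Zap70 reached at most 3.32 CPM in any library, and all 4 were higher in DCKO 1 than in DCKO 2 (camera adjusted p = 0.0451; adjusted p = 0.624 with an estimated correlation). Among other fits, this call was lost without Control 3 (adjusted p = 0.235), without DCKO 1 (adjusted p = 0.251) and with the filter of at least 1 CPM in 2 libraries, which left 3 genes (median 0.02, adjusted p = 0.735). Against no change, the list did not pass fry (adjusted p = 0.111). Without Control 1, Control 2 or DCKO 1, 1, 0 and 0 of these genes were higher. Erythroid, platelet and stromal genes had 2 of 14 higher (Car2, 1.01, and Kdr, 4.04 at under 1.3 CPM), with 12 not past the test, as when adjusted over the list alone (camera adjusted p = 0.381). The calls of all 9 marker genes named here were lost in at least 1 fit that left out a library. None of the 4 tested sex-linked transcripts passed (camera adjusted p = 0.736). Y-linked transcripts had 12513 counts in Control 3, 10493 in DCKO 2, 11 in DCKO 1 and 0 in the other libraries. With a term for these transcripts, 839 genes were higher and 545 lower, and without Control 3 and DCKO 2, which held them, 1869 were higher and 1896 lower. That fit had a single DCKO library, so its spread came from Control 1 and 2 alone.

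**Figure D3:**
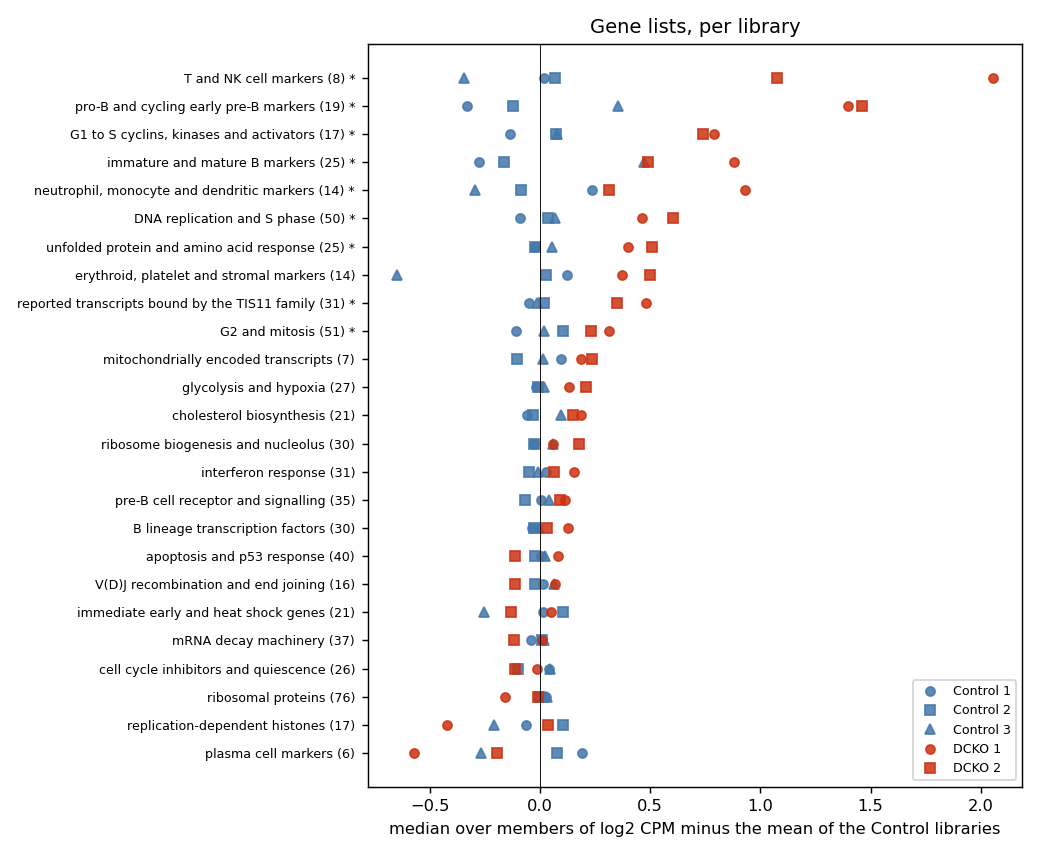
Median over the tested members of each gene list (number in brackets) of log2 CPM minus the mean of the Control libraries, 1 symbol per library, blue for Control and red for DCKO, with an asterisk where camera passed at the preset correlation. For the pro-B and early pre-B list the DCKO libraries lie at 1.40 and 1.46 and Control 3 at 0.35.

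Genes called higher in DCKO carried AU-rich sequence in the 3' UTR more often than genes not called. The heptamer TATTTAT was found in 37.8% of 1091 searched genes called higher and in 27.2% of 9351 not called. After adjustment for UTR length, AT share and expression the odds ratio was 1.42 (95% interval 1.23 to 1.65; p = 2.11e-06 by logistic regression across n = 10442 genes, which are not independent replicates). None of the 20 other arrangements of these bases gave as high an odds ratio, the highest being 1.20. Of 785 searched genes called lower, 25.4% carried the heptamer, with an odds ratio of 0.88 (95% interval 0.73 to 1.06; n = 10136 genes, p = 0.173), and 10 of the 20 other arrangements gave an odds ratio as high.

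**Figure D4:**
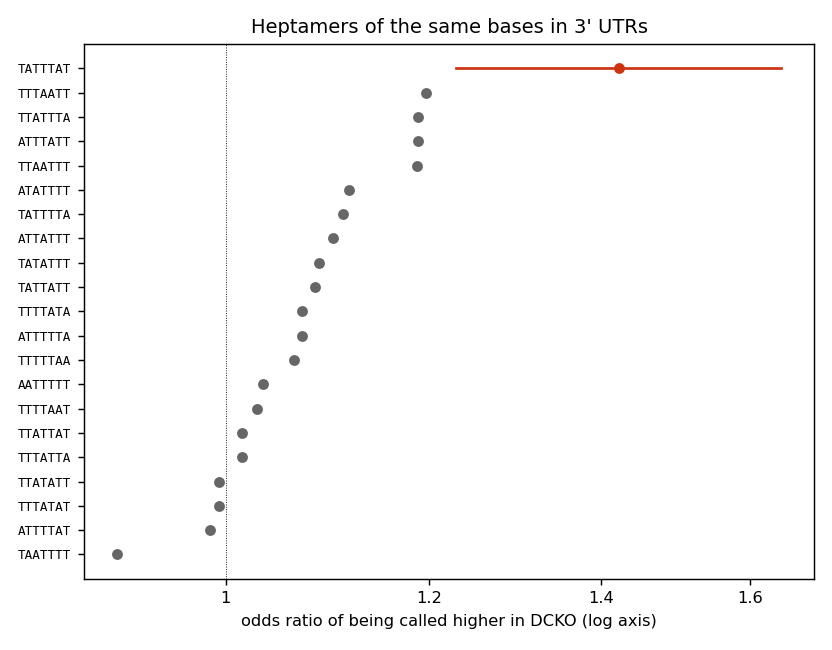
Odds ratio (log axis) of being called higher in DCKO for genes whose longest 3' UTR holds each of 21 heptamers made of the same bases, 1 point per heptamer; the line spans the 95% interval for TATTTAT. TATTTAT lies at 1.42 and the other 20 arrangements at 1.20 or below.

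Few immunoglobulin genes were in the count table. The only tested kappa V gene, Igkv4-69, was at 0 counts in both DCKO libraries and at 0.311 CPM in Control, at least 3.84-fold lower against a floor of 3 counts per library (edgeR adjusted p = 0.0339), a call lost without Control 2 or either DCKO library. Without Control 1 or Control 3 the gene did not pass the count filter. With 1 gene the list had no camera test, and the gene was also lower adjusted over the list alone. Neither of 2 heavy chain V genes, Ighv3-5 (log2 fold change 0.67) and Ighv1-73 (-2.19), passed, also adjusted over the list alone; their median and mean were below 0 while camera's direction was up (adjusted p = 0.903). Of 2 constant and lambda genes, which are near-identical, 1 was lower (Iglc3, -0.57), and 2 when adjusted over the list alone (camera adjusted p = 0.197; adjusted p = 0.0265 without Control 2); the call of Iglc3 was lost without any 1 library. All 10 immunoglobulin genes of the table together were at 92.9 ± 17.8 CPM (SD, n = 3) in Control and 61.5 ± 9.52 CPM (SD, n = 2) in DCKO (exact two-sided permutation p = 0.2; smallest possible 0.1). Both DCKO libraries (54.7 and 68.2 CPM) lay below the lowest Control library (74.0 CPM).

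The authors' deposited table called 1070 genes higher and 694 lower in DCKO at an adjusted p threshold of 0.05. Of these, 951 and 638 were also called in the same direction by edgeR here (90.1%), and 0 in the opposite direction. Log2 fold changes of the authors' deposited table and of the edgeR fit had a Spearman correlation of 1.0 over 11369 genes, as both use the same counts.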

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

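The term for Y-linked transcripts and the fit without the libraries that hold them were chosen after the data were seen. Other scaling or filter choices, other tools and left-out libraries turned the direction of 0 called genes. The groups did not overlap in CPM for any called gene, so this outcome was nearly fixed in advance. Leaving out 1 library gave 238 to 1381 genes higher and 137 to 1012 lower; fewer libraries leave fewer degrees of freedom, and a lone DCKO library was assumed to vary like the Control libraries. DESeq2 called 1548 higher and 1281 lower, and the fit without the Y-linked libraries 1869 and 1896; the cause was not tested. With the replicate block, 1468 genes were higher and 1266 lower, 3 V(D)J recombination and end joining genes were lower, camera did not pass for T and NK cell genes (adjusted p = 0.207), and it passed for the pre-B cell receptor (adjusted p = 2.02e-04), B lineage transcription factor (adjusted p = 0.00688) and sex-linked (adjusted p = 1.29e-24) lists. Same-numbered libraries did not deviate together (correlations 0.019 and -0.063 over genes). This cannot exclude a pairing, since deviations of the 2 DCKO libraries from their mean mirror each other (correlation -1). In the replicate block Control 3 had no DCKO partner and did not enter the contrast. The sex-linked list was therefore compared there between DCKO and Control libraries with 0 Y-linked counts. Of 93 called genes named in the text, 39 kept their calls with every single library left out and under each other setting; 51 calls ended without DCKO 1, 41 without Control 2, 30 without Control 1, 25 without DCKO 2 and 5 without Control 3. Zfp36l1 ranged from -5.28 to -4.71 and Zfp36l2 from -3.21 to -2.71 over left-out libraries. Zfp36, which was not called, ranged from -0.13 to 0.13 over left-out libraries, and was 0.0212 with the Y-linked term and 0.0128 without the Y-linked libraries. The call of mt-Nd1 was gained with DESeq2 alone.

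Of the 9 lists higher by camera at the preset correlation, 0 passed with an estimated correlation. The list of the targeted genes, lower in DCKO, did not pass with an estimated correlation either (camera adjusted p = 0.29). Genes of a list moving together do not alone account for this. The reported-bound list had an estimate of 0.004, below the preset 0.01, yet its unadjusted camera p rose from 0.00158 to 0.0425. For 40 changed genes simulated independently of each other, the camera p rose from 1.1e-17 to 0.00625. By fry, against no change, the G1 to S and the amino acid and unfolded protein response lists (adjusted p = 0.0264 each) and the pro-B list (adjusted p = 0.0273) passed. So did the DNA replication and reported-bound lists (fry adjusted p = 0.0406 each). The G2 and mitosis, immature and mature B, T and NK cell, and neutrophil, monocyte and dendritic lists did not. The odds ratio of TATTTAT in genes called lower, 0.88, was 1.12 with the nonamer TTATTTATT, 1.19 at an adjusted p threshold of 0.01, 0.78 with the shortest annotated 3' UTR (n = 10136 genes, p = 0.0341), and 0.882 to 1.19 over left-out libraries; the cause was not tested. That for genes called higher stayed above 1 and past the threshold, from 1.22 to 1.87. Agreement with the deposited table was 33.6% at an adjusted p threshold of 0.01, where edgeR called 246 genes higher and 116 lower and the authors' deposited table listed 687 and 377. The immunoglobulin share difference was -31.4 CPM, and -31.8 without mitochondrial and ribosomal protein genes. Depth limits genes near the floor, such as Thy1 and Il2rb.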

Other observations

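The gene family scan, the analysis of genes at 0, the check of earlier-stage and of neutrophil and monocyte genes, and the genes named in this part were chosen after results had been seen. Among gene families taken by the letters that start their symbols, with at least 8 tested members, those starting with Cd were called higher more often than other genes. Of 54 tested, 17 were higher (31.5%, one-sided Fisher exact p = 6.86e-06, Benjamini-Hochberg adjusted 0.00279 over 406 tests of families and directions). Another 5 were lower (9.3%), among them Cd72 and Cd79a, which carries cre in DCKO. The genes called higher included markers of other cells, such as Cd4, highest in DCKO 1, and Cd300lf, at 0 counts in Control. Besides Cd22 and Cd40 they included the scavenger receptor gene Cd36 (44.3 against 434 CPM, log2 fold change 3.29), the adhesion receptor gene Cd44 (0.50) and Cd200 (2.00). The call of Cd44 was lost without DCKO 1 and that of Cd200 without Control 1, Control 2 or DCKO 1. No other family passed this adjustment; the next were ATPase, interleukin and Mcm genes among those called higher (adjusted p = 0.138 each by Fisher's exact test).

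Some genes had reads in 1 group alone. Serpinh1 and Mtus1 had 0 counts in Control and were at least 32.2-fold and 23.3-fold higher in DCKO against a floor of 3 counts per library, and Mag and Asb10 had 0 counts in DCKO and were at least 22.8-fold and 15.9-fold lower. Of the 220 tested genes within 10 Mb of Cd79a, which carries cre, 18.6% were called, against 16.5% of the 11186 others (odds ratio 1.16, 95% interval 0.80 to 1.64; Fisher exact two-sided p = 0.41).

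The pro-B and early pre-B list was higher in DCKO, with a median log2 change of 1.45 (9 of 19 genes called). A difference in sex between the animals is argued against, since with a term for Y-linked transcripts the median was 1.51 and camera passed at the preset correlation (adjusted p = 1.92e-16), although without the term the list did not pass with an estimated correlation (adjusted p = 0.29). Another candidate explanation is more cells of an earlier stage inside the CD43 negative, CD25 positive gate. Across the 19 list genes, the CPM difference of Control 3 over Control 1 ranked like that of DCKO 1 over Control 2 (Spearman rho 0.71, permutation p = 0.0011), and 16 were higher in Control 3, which met the mark set for that explanation; but lists matched on expression gave a lower rho in only 93.4% of 2000 draws, and on log2 ratios rho was 0.44 (permutation p = 0.0643). It therefore stays open beside an effect on these genes of the deletion or of cre at the Mb1 locus, which the design cannot separate from it.

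Siglech, Tlr7 and Mpeg1 were higher in DCKO (Tlr7 log2 fold change 2.74, Mpeg1 2.22) and highest in DCKO 1. The calls of all 3 were lost without Control 2, and those of Siglech and Tlr7 also without DCKO 1. Neutrophils or monocytes may contribute. Their 7 markers under 5 CPM in Control had a median log2 ratio of DCKO 1 over DCKO 2 of 1.17. This met the mark set for them, but it was the value of Fcgr3, at 0.67 and 0.242 CPM in these libraries. Of the 7 markers, 4 were under 1 CPM in DCKO 1. Mpo was at 53.2 CPM in DCKO 1 and 0 in DCKO 2 and Ccr2 at 5.84 and 0.404 CPM. But S100a8, S100a9 and Lyz2, abundant in mature cells of these types, reached at most 0.475 CPM in DCKO 1. F13a1 and Itgam, above the 5 CPM limit in Control, were not higher in DCKO 1 (49.7 and 181 CPM) than in DCKO 2 (51.3 and 276 CPM). The values thus point both ways. Plasmacytoid dendritic cells may contribute: their 10 other markers had a median ratio of 0.82, above 99.6% of random lists but below the 1 set in advance. The DCKO libraries also differed in Y-linked counts, 11 in DCKO 1 and 10493 in DCKO 2. Mpo was at 4.25 and 3.48 CPM in Control 1 and 2, without Y-linked counts, and at 0.103 CPM in Control 3, which held them. Siglech did not follow that split in Control, at 2.39, 0.101 and 0.283 CPM in Control 1, 2 and 3. Cells of either kind, a difference between the animals and a change of the genes in pre-B cells therefore cannot be told apart. The CD19 gate would remove most cells of either kind.

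Genes with the heptamer TATTTAT were called higher in DCKO more often than others. The listed genes of the cell cycle, replication, mitosis and histones do not alone account for it, as the odds ratio without them was 1.47 (95% interval 1.26 to 1.70). Leaving them out kept 1033 of the 1091 searched genes called higher, so the odds ratio could hardly have moved far. Cell cycle genes outside these lists stayed in, and their part was not tested. General T-rich and A-rich sequence of the 3' UTR does not alone account for the value of the heptamer. Of the 20 other arrangements of its bases, 0 gave as high an odds ratio, and their median was 1.07. The shorter ATTTA, which lies within the heptamer, had an odds ratio of 1.553 (95% interval 1.287 to 1.875). The longer TTATTTATT had 1.34 (95% interval 1.081 to 1.661). Neither was ranked against arrangements of its own bases, so general sequence is not excluded for them. The association is thus not particular to the heptamer. Loss of decay through these proteins is a hypothesis that these values are consistent with; mRNA stability was not measured here.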
